A study of Mus musculus with 8 samples.

How the data were processed

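Total RNA of whole mouse skin was measured on 8 one-colour microarrays, 4 of skin that the labels call Control and 4 of skin that they call DTG, an abbreviation the labels do not spell out. Per the labels' protocols and the series' design text, tissue was frozen, RNA was extracted with TRIzol and amplified, and Cy3-labelled cDNA was hybridised. Groups were taken from the tissue label of each sample, and replicates were numbered 1 to 4 within each group in deposit order, so the numbers name samples and mark no shared animal. In both groups they equal the array's slide column. All 8 samples are labelled male, but 2 sex-linked genes read as female on 5 arrays (see Results). The labels speak of 4 skins per group and do not state whether they came from separate animals. By those 2 genes each group held both sexes, and so more than 1 animal. The p-values measure only the spread between these samples, which may be partly technical. All arrays lay on 1 slide with the same scan time. The Control arrays occupied row 1 and the DTG arrays row 2 of that slide, so slide row and group cannot be told apart.

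Each array's deposited scanner output gives spot brightness as an intensity on a linear scale, made with Agilent Feature Extraction, version 11.5.1.1 per the file headers and 10.7 per the submitters' processing notes. The processed signal used here is the software's background-corrected intensity, and the software reports statistics of spatial detrending, per the file headers. Flags for outlier spots and for spots well above background are other columns of the same tables, deposited by the authors. The headers name genome build mm9, and no coordinates were used. The authors' deposited value table for the whole series covers 43861 probes on a linear intensity scale. Of its 350888 values, 99.6% lay within a relative tolerance of 0.001 of the mean processed signal of that probe, so it is neither log-transformed, centred nor scaled between arrays. It served only as an alternative.

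The arrays carry 62976 spots, of which 59305 are not controls, for 55681 probes. The scanner tables hold accessions and no gene symbols. Accessions, without versions, were matched to a RefSeq gene table, assembly GRCm38.p6, which was used for names only. This named 26762 probes (48.1%) and 20284 genes, and left 28919 probes unnamed. Named probes entered the comparison. Unnamed probes were tested in a separate fit.

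Signals were put on the log2 scale, and each array's 75th percentile over non-control probes was subtracted. Outlier-flagged spots were left out (0.55% of probe values) and spots of 1 probe were averaged. Probes were kept if well above background on at least 3 of the 4 arrays of at least 1 group. Of several kept probes of a gene, the one with the highest mean signal stood for the gene, and disagreeing probes are given with the genes named. DTG was compared with Control by limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 (data.table, version 1.17.8), with Benjamini-Hochberg adjustment over 17736 genes and calls at an adjusted p under 0.05. Log2 fold changes are DTG minus Control, with the standard error (SE) of the fit. Levels are log2 signal relative to the array's 75th percentile, as mean ± SD. Where no array of a group was well above background, or the group's mean lay below the mean of the lowest signals well above background, the fold is a bound, written "at least N-fold". It sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal well above background. The 2 Msi1 and 2 Msi2 probes were also compared by exact two-sided permutation tests, whose smallest possible p with 4 arrays against 4 is 0.0286. The number of arrays limits the precision; the median SE of a gene's log2 fold change was 0.14.

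Of 35 gene lists written from textbook knowledge, 33 were tested with limma's camera at its preset inter-gene correlation of 0.01. That test ran on the 17287 genes (97.5%) with values on all 8 arrays and was adjusted over the 33 lists. The Musashi family and the sex-linked genes were read per gene. Camera with an estimated correlation and fry, which asks whether a list's genes moved one way without comparing them with other genes, were run beside it. The rule for naming genes took Msi1 and Msi2, then the 10 largest changes in each direction among called genes whose groups did not overlap, leaving out predicted and clone names, then up to 4 members of each list with the smallest p. It named 151 genes, a few of which are not reported here. The groups, the test, the lists, this rule and all alternative settings except those said to be later were chosen before the data were examined. That design assumed gene names in the scanner tables and a mean signal column for normexp. Accessions and the median signal were used in their place.

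Alternative settings were quantile scaling, median scaling, no scaling, normexp background correction with offset 50, the authors' deposited value table, no filter on dim probes, and probes well above background on all 8 arrays. Others were the average of a gene's probes, every probe on its own, eBayes with trend and robust, array weights, slide column as a block, each array left out in turn, both other list tests and stricter thresholds. With every probe on its own, the probe with the smallest p gave the value of a named gene. Alternatives chosen after seeing the data were a covariate for high or low Xist, each Xist class alone, scaling on 10 spike-in probes, probes above background on all arrays with the arrays centred on them, and outlier spots kept.

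The procedure was tested on simulated data for DTG against Control, with 17287 genes and 50 genes changed at each size. It recovered 26% of genes changed by 0.5 on the log2 scale, 72% at 1, 90% at 2 and 100% at 3, with 5 unchanged genes called. A cell cycle list moved by -0.5 was called, and 0 of the other lists were. The simulated noise was independent between genes, and far fewer genes were changed than the data called. In the data the estimated correlation within a list reached 0.83. The simulation therefore shows how the procedure behaves for independent genes, and cannot show how often lists are called wrongly on these arrays.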

Results

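Gene expression in whole skin was measured on 8 one-colour oligonucleotide arrays, 4 Control and 4 DTG. The series title names overexpression of Musashi1, an RNA-binding protein encoded by Msi1, in mouse skin. The comparison therefore asks which transcripts differ between DTG skin and Control skin. Array measures differed with the group. The share of spots well above background was 82.7% ± 2.64 (SD, n = 4) in Control and 69.8% ± 1.23 (SD, n = 4) in DTG, with no overlap (exact two-sided permutation p = 0.0286, adjusted over 5 measures 0.0357). The mean log2 signal of the negative-control spots was 2.85 in Control and 4.46 in DTG. The spike-in signal relative to each array's 75th percentile was -0.64 in Control and -1.13 in DTG. For both, the exact two-sided permutation p was 0.0286, adjusted 0.0357. The 75th percentile itself, at 11.85 and 11.97, did not differ beyond the spread (exact two-sided permutation p = 0.229). The scanner software's own limits for negative-control spread and for spatial detrending were exceeded on 4 DTG and 0 Control arrays, and all 8 arrays missed its limit for the spike-in slope. Correlations of probes across array pairs were 0.981 to 0.992 within Control, 0.984 to 0.990 within DTG and 0.960 to 0.978 between groups; they are across genes, which are not independent replicates. No array was a copy of another.

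**Figure D1:**
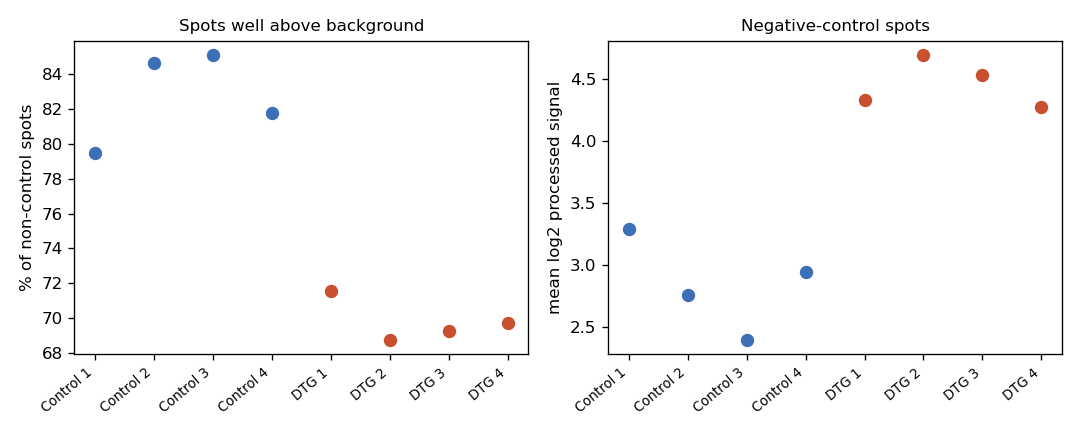
Left, percentage of non-control spots well above background; right, mean log2 processed signal of the negative-control spots; 1 point per array, Control in blue and DTG in red, with vertical axes that do not start at 0. DTG arrays lie at 68.8 to 71.6% against 79.5 to 85.1% for Control, and their negative-control spots are brighter.

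All 8 samples are labelled male. Xist, the RNA that coats the inactive X chromosome, was high on 5 arrays (Control 2 and 4, DTG 1, 3 and 4) and low on 3 (Control 1 and 3, DTG 2). Eif2s3y, a Y-linked gene, was low on the 5 arrays (-7.79 to -6.18) and high on the 3 (1.22 to 1.66). By these 2 genes the 5 arrays read as female skin and the 3 as male skin, so the male label does not match the 5. Xist levels were 0.73 and 0.62 on Control 2 and Control 4 against -8.56 and -6.89 on Control 1 and Control 3. With the Xist class as a covariate 5934 genes were called between DTG and Control. Within the arrays of high Xist the count was 2637, and within those of low Xist, where 1 DTG array was assumed to vary like the others, it was 715. The Msi1 change was 7.75 and 5.87 in these classes. The high class holds Control 2, whose Msi1 level was -5.92 against -1.56 on Control 4. The gap between the 2 changes therefore cannot be read as an effect of sex.

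**Figure D2:**
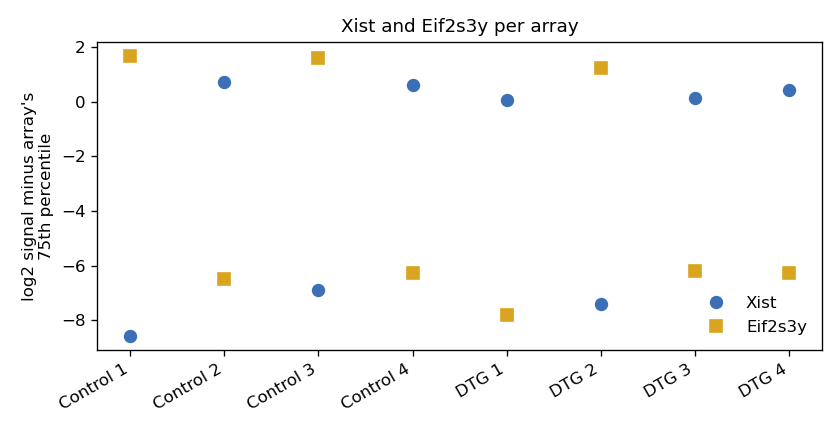
Log2 signal relative to the array's 75th percentile for Xist (blue circles) and Eif2s3y (yellow squares) on each of the 8 arrays. The 5 arrays with high Xist have low Eif2s3y, and the 3 arrays with low Xist have high Eif2s3y.

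Msi1 was far higher in DTG skin on 1 of its 2 probes. On probe A_55_P2062688 the level was -2.80 ± 2.11 (SD, n = 4) in Control and 4.01 ± 0.16 (SD, n = 3) in DTG, where the spot of DTG 1 was left out for an outlier flag. The log2 fold change was 6.81 (SE 1.02, 112-fold, limma adjusted p = 0.0029), and every DTG array lay above every Control array (exact two-sided permutation p = 0.0286 over 35 orderings, the smallest possible). With the DTG 1 spot kept, the change was 6.87, and without Control 2 it was 5.77. The Control arrays were uneven on this probe, with -5.92 on Control 2 and -2.26, -1.48 and -1.56 on Control 1, 3 and 4. The other Msi1 probe, A_51_P296866, read -3.11 ± 0.23 (SD, n = 4) in Control and -3.13 ± 0.15 (SD, n = 4) in DTG (exact two-sided permutation p = 1). Averaged over the probes with a value on each array, which on DTG 1 left A_51_P296866 alone, the change was 2.50 and did not pass (adjusted p = 0.060). Which part of the transcript each probe covers was not analysed here. Msi2, the related Musashi gene, fell by 0.55 (SE 0.08, adjusted p = 0.0024) on its brighter probe. Its dimmer probe moved the opposite way, by 1.09 (SE 0.14).

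**Figure D3:**
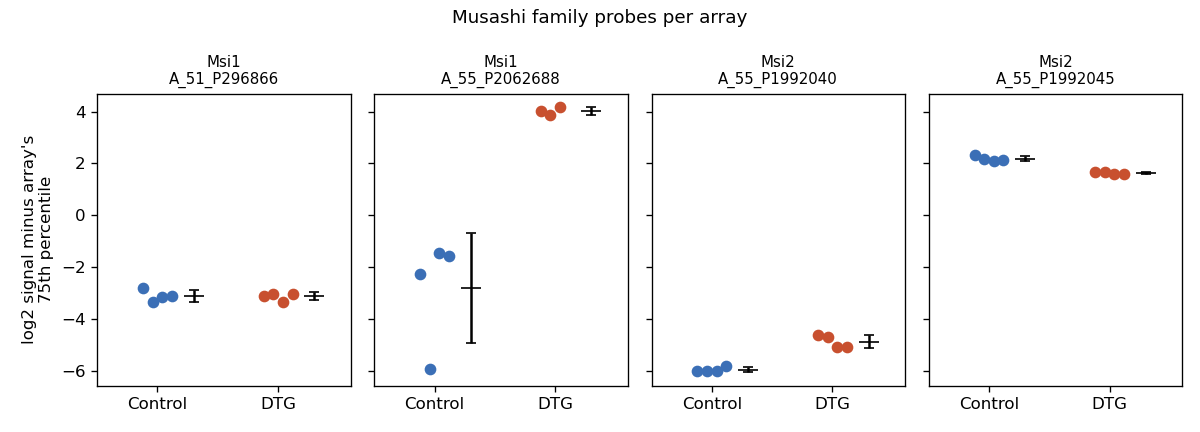
Log2 signal relative to the array's 75th percentile for the 2 Msi1 and 2 Msi2 probes, 1 point per array (Control blue, DTG red), with the mean ± SD as a black bar. Msi1 probe A_55_P2062688 rises from a mean of -2.80 to 4.01 (3 DTG points, 1 outlier spot left out), the other Msi1 probe does not separate the groups, and the 2 Msi2 probes move in opposite directions.

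Beyond Msi1, and relative to other genes, lists of mitotic and of Wnt pathway genes were lower in DTG skin and lists of inflammatory, wound-associated, p53-associated and immediate early genes were higher. These are calls of camera at a preset correlation, and none held with an estimated one (smallest camera adjusted p = 0.632 with an estimated correlation). Fry did not call the inflammatory and wound lists. Of the 35 splits of the 8 arrays into 4 and 4, 15, the real one included, called at least 9 lists, as many as here. The number of list calls is therefore not beyond chance. Kif23, a mitotic kinesin, fell by 1.39 on the log2 scale (SE 0.11, n = 4 per group). Cxcl5, a neutrophil-attracting chemokine, rose by 3.49 (SE 0.41), and Ptgs2, the inducible cyclooxygenase, by 2.66 (SE 0.29). Of 17736 genes tested, 5755 (32.4%) were called, 1977 higher and 3778 lower in DTG. At an absolute log2 fold change of 1 or more there were 1214, of which 620 were higher and 594 lower. The groups did not overlap in 6125 tested genes (34.5%), against 2.86% by chance. The direction split depends on the scale: 65.6% of calls were lower here, 41.7% without scaling and 6.86% with the arrays scaled on spike-in spots. Over all tested genes the median log2 fold change was -0.15 here and 0.34 on the spike-in scale, so list medians below are relative to the median of all genes. The other scalings except quantile shift each array by 1 number, so they leave such a median nearly unchanged by construction. Of the other scalings, only quantile scaling can move it.

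Among the 10 largest increases were genes with little signal in Control skin. Prl2a1, of the prolactin family, was at least 36.8-fold higher, the tight-junction gene Cldn17 at least 53.4-fold and the metalloendopeptidase gene Kel at least 4.65-fold, each with 0 of 4 Control arrays well above background. Afp, the fetal serum protein alpha-fetoprotein, rose by 6.27 (SE 0.16, adjusted p = 8.9e-07), with 2 of 4 Control arrays above background. Gstt4 was at least 27.5-fold and Erich3 at least 25.5-fold higher, each with 1 of 4 Control arrays above background. Prl7b1 rose by 5.30 and Wincr1 by 5.09, with 2 and 3 Control arrays above background. Ascl3, a basic helix-loop-helix transcription factor gene, was measured on every array and rose by 4.93 (SE 0.17). Among the 10 largest decreases, Mt4, a metallothionein gene of stratified epithelia, was at least 15.6-fold lower, Wnt3a at least 2.67-fold and the potassium channel gene Kcnj16 at least 1.84-fold, each with 0 of 4 DTG arrays well above background. Pyy, which encodes peptide YY, fell by 3.94 (SE 0.64), Il20ra, a receptor subunit for interleukin 20, by 3.74 (SE 0.39) and Nat8l by 3.34 (SE 0.31). Lama1, a laminin chain gene, fell by 3.13, Scgb1b27 by 3.04 and Gadl1 by 2.92, and Mgarp was 8.02-fold lower. Il20ra and Lama1 were above background on 3 of 4 DTG arrays. Ranks follow the fitted changes, which exceed the bounds of the genes given as bounds, so Kel, Wnt3a and Kcnj16 would not rank here by their bounds. Of all called genes, 562 had no DTG array and 13 no Control array well above background.

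Of 33 gene lists tested, 9 were called, 5 higher and 4 lower in DTG, and 11 had an unadjusted p under 0.05. With an estimated correlation 0 were called by camera, 1 had an unadjusted p under 0.05 and the smallest adjusted p was 0.632. Fry called 13 lists, among them 6 of the 9 but not the inflammatory (fry adjusted p = 0.132), wound (0.138) and barrier lipid (0.122) lists. The lists it called beyond the 9 were all lower in DTG: adipocyte (fry adjusted p = 0.0023), Schwann cell and nerve, skeletal muscle and Notch (0.0032 each), Hedgehog (0.0072), dermal extracellular matrix (0.039) and hair follicle stem cell (0.045). Fry takes no account of the shift of all genes, and the own medians of these lists were 0.08 to 0.33 on the spike-in scale. List p-values without a named tool are those of camera. The cell cycle list fell as a group: 31 of 43 members fell, 0 rose and 12 did not pass (adjusted over the list alone, 32 lower and 1 higher). Its median relative to all genes was -0.54, and -0.59 with quantile scaling (camera adjusted p = 1.3e-07, and 0.812 with an estimated correlation). The list's own median was below 0 under each scaling, at -0.20 on the spike-in scale. The spindle genes Nusap1, Bub1b and Bub1 fell by 1.03 (SE 0.09), 1.44 (SE 0.14) and 1.36 (SE 0.13). The p53 and cell cycle arrest list rose, with 11 of 24 members higher, 1 lower and 12 that did not pass (adjusted over the list alone, 11 higher and 3 lower). Its median was 0.31 (adjusted p = 0.00043; adjusted p = 0.812 with an estimated correlation). Pmaip1, a pro-apoptotic BCL2 family gene, rose by 1.51 (SE 0.13), Plk3 by 1.14 (SE 0.19), Plk2 by 0.98 (SE 0.09) and Cdkn1a, the cyclin-dependent kinase inhibitor p21, by 0.92 (SE 0.16). The immediate early and heat shock list, written as a check on tissue sampling, was also called higher. In it 7 of 24 members rose, 0 fell and 17 did not pass (adjusted over the list alone, 7 higher and 0 lower), with a median of 0.33, or 0.21 without Control 3 (adjusted p = 0.00092; adjusted p = 0.838 with an estimated correlation). Fosl1 rose by 2.41 (SE 0.31), Zfp36 by 1.32 (SE 0.14), Ier3 by 1.20 (SE 0.18) and the heat shock gene Hspa1a by 0.80 (SE 0.18).

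**Figure D4:**
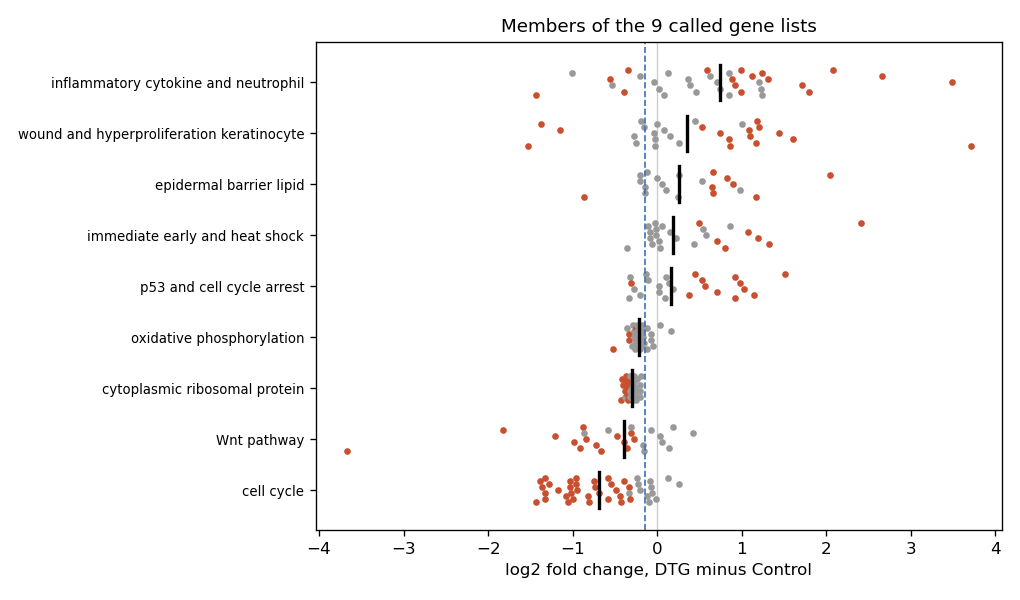
Log2 fold change, DTG minus Control, of each member of the 9 called gene lists (red, adjusted p under 0.05; grey, not called), with the list median as a black bar and the median of all genes, -0.15, as a blue dashed line. The cell cycle members lie mostly to the left and the inflammatory members mostly to the right; with spike-in scaling the Wnt, ribosomal protein and oxidative phosphorylation medians turn positive, at 0.10, 0.19 and 0.27, and with quantile scaling the last 2 lie above the median of all genes.

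Camera also called the inflammatory, wound and barrier lipid lists higher, each with members in both directions. Of 35 inflammatory cytokine and neutrophil genes, 13 rose, 4 fell and 18 did not pass (adjusted over the list alone, 13 higher and 4 lower), with a median of 0.89 (adjusted p = 0.00034; adjusted p = 0.902 with an estimated correlation). The list was not called on the spike-in scale (camera adjusted p = 0.106), which leaves its median relative to all genes unchanged by construction. With quantile scaling that median was 0.87. Besides Cxcl5 and Ptgs2, Il23a rose by 1.12 (SE 0.18), while Il17a, a T cell cytokine gene, was called lower (adjusted p = 0.00053) with 0 of 4 DTG arrays above background. Its Control mean, -6.29, lay below the mean of the lowest DTG signals above background, -5.40, so no fold bound can be given. Of 28 wound and hyperproliferation keratinocyte genes, 12 rose, 3 fell and 13 did not pass (adjusted over the list alone, 13 higher and 3 lower). The median was 0.50 (adjusted p = 0.00043; adjusted p = 0.975 with an estimated correlation). The EGF receptor ligand genes Hbegf, Areg and Ereg rose by 1.61 (SE 0.15), 1.45 (SE 0.25) and 0.86 (SE 0.16), and Sprr2h, a cornified envelope precursor gene, was 2.15-fold higher. Of 20 epidermal barrier lipid genes, 7 rose, 1 fell and 12 did not pass (adjusted over the list alone, 7 higher and 1 lower), with a median of 0.40 (adjusted p = 0.0064; adjusted p = 0.902 with an estimated correlation). Degs2, a ceramide-forming desaturase gene, rose by 2.04 (SE 0.33), Cyp4f39 by 1.17 (SE 0.17) and Sptlc1, a subunit of serine palmitoyltransferase, by 0.66 (SE 0.10). The alkaline ceramidase gene Acer1 fell by 0.86 (SE 0.11).

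**Figure D5:**
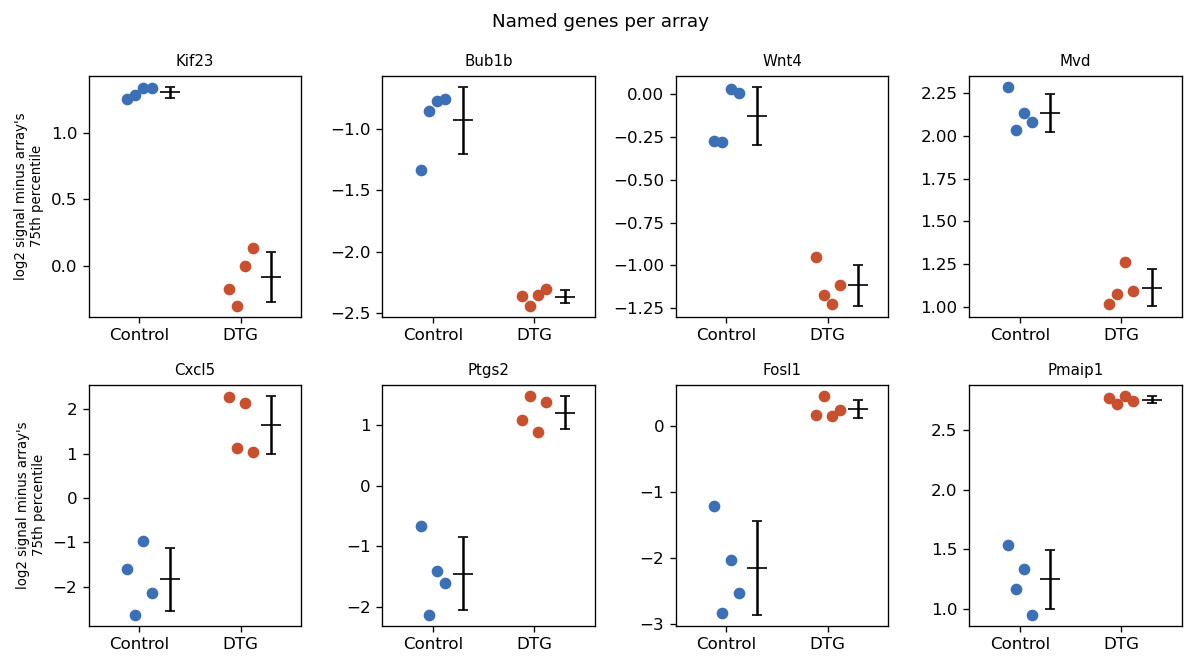
Log2 signal relative to the array's 75th percentile for 8 named genes, 1 point per array (Control blue, DTG red) with the mean ± SD as a black bar, each panel on its own vertical axis. Kif23, Bub1b, Wnt4 and Mvd are lower and Cxcl5, Ptgs2, Fosl1 and Pmaip1 higher on all 4 DTG arrays; these 8 were picked for display from the named genes.

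In the Wnt pathway list 14 of 25 members fell, 0 rose and 11 did not pass (adjusted over the list alone, 16 lower and 0 higher). The median was -0.24 relative to all genes under the scale used (camera adjusted p = 0.017, and 0.632 with an estimated correlation). With quantile scaling that median was -0.30. On the spike-in scale, which cannot move the median relative to all genes, the list's own median was 0.10. The call was lost with genes above background on all 8 arrays, with the average of probes and within the arrays of low Xist. There the median of the members in the test, relative to all genes, was -0.20, -0.19 and -0.12, against -0.21 with the settings used. Wnt4, a secreted ligand, fell by 0.99 (SE 0.11). Znrf3, a feedback inhibitor of Wnt signalling, was at least 1.82-fold lower with 0 of 4 DTG arrays above background. Nkd1, another inhibitor, fell by 0.91 (SE 0.16), and its other probe read 0.27 (SE 0.66). The Notch list was not called by camera (adjusted p = 0.952) but was called lower by fry, with a median of -0.01 relative to all genes: of 19 members 1 rose, 5 fell and 13 did not pass (adjusted over the list alone, 1 higher and 6 lower). The ligand gene Jag2 fell by 1.24 (SE 0.11), Dtx1 by 0.84 (SE 0.10) and the receptor gene Notch3 by 0.57 (SE 0.13). Numb, a Notch inhibitor whose mRNA is a known Musashi1 target, rose by 1.59 (SE 0.20). In the Hedgehog list, also called by fry alone, 3 of 12 fell (2 adjusted over the list alone; adjusted p = 0.429). Gli3 and Cdon each fell by 0.57, Boc by 0.34 (0.15 on the spike-in scale), and Gli1 read -0.49 (adjusted p = 0.052). In the BMP and TGF-beta list 1 of 18 rose and 3 fell (the same counts adjusted over the list alone; adjusted p = 0.818). Bmp4, Tgfb2 and Bmp7 fell by 0.91, 0.90 and 0.80, and the BMP antagonist gene Nog rose by 0.54.

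Changes of ribosomal and respiratory chain genes were small. Of 33 cytoplasmic ribosomal protein genes, 12 fell, 0 rose and 21 did not pass (adjusted over the list alone, 26 lower and 0 higher). The median was -0.15 relative to all genes and 0.01 with quantile scaling, and on the spike-in scale its own median was 0.19 (adjusted p = 0.00062; adjusted p = 0.975 with an estimated correlation). Rps18, Rpl30, Rpl18 and Rpl3 fell by 0.42, 0.42, 0.38 and 0.35, and read 0.07, 0.06, 0.10 and 0.14 on the spike-in scale. Of 34 oxidative phosphorylation genes, 4 fell, 0 rose and 30 did not pass (adjusted over the list alone, 1 lower and 0 higher). The median was -0.07 relative to all genes and 0.04 with quantile scaling, and on the spike-in scale its own median was 0.27 (adjusted p = 0.024; adjusted p = 0.975 with an estimated correlation). Atp5d fell by 0.52, while Sdhb, Atp5g1 and Uqcrc1 fell by 0.33, 0.33 and 0.25 and were above 0 on the spike-in scale. Without Control 1 the ribosomal protein median was -0.10. The oxidative phosphorylation median was -0.04 without Control 1, -0.11 without Control 2 and -0.12 without Control 4. Neither list was called with quantile or spike-in scaling or within the arrays of high Xist. The oxidative phosphorylation call was also lost without scaling, with the Xist covariate, and without Control 1, Control 3, DTG 2 or DTG 3. Sterol biosynthesis genes went both ways, with 3 of 24 higher and 5 lower (the same adjusted over the list alone; adjusted p = 0.818). The mevalonate pathway genes Mvd and Mvk fell by 1.02 (SE 0.10) and 1.04 (SE 0.11), and Tm7sf2 by 1.18 (SE 0.12).

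Camera called no list of markers of other cell types in skin, whereas fry called the adipocyte, Schwann cell, skeletal muscle and dermal matrix lists lower. Of 29 adipocyte genes 13 fell and 16 did not pass (13 lower adjusted over the list alone, camera adjusted p = 0.085). The list median relative to all genes was -0.19 with the scale used and -0.13 with quantile scaling. Plin1, which coats lipid droplets, fell by 1.35 (SE 0.22), Cyp2e1 by 1.56 (SE 0.28), Acacb by 1.26 (SE 0.11) and the glucose transporter gene Slc2a4 by 0.55 (SE 0.09). Of 18 Schwann cell and nerve genes 7 fell (7 adjusted over the list alone, camera adjusted p = 0.085). The median relative to all genes was -0.26 with the scale used and -0.33 with quantile scaling. S100b, Prx and Ncmap fell by 0.60, 0.70 and 0.49, and a second Ncmap probe read -0.53 (SE 0.20) and was not called. Of 32 skeletal muscle genes 1 rose and 9 fell (the same adjusted over the list alone; adjusted p = 0.364). Tnnc1, Eno3, Tnni2 and Tnnt3 fell by 0.48, 0.45, 0.40 and 0.34 and were at 0.001 to 0.14 on the spike-in scale. Of 24 dermal extracellular matrix genes 6 fell (0 adjusted over the list alone; adjusted p = 0.428). Postn, Fn1, Lum and Fbln1 fell by 0.38, 0.39, 0.31 and 0.30 and turned positive on the spike-in scale. A second Fbln1 probe read -0.20 (SE 0.33) and was not called. Of 15 smooth muscle and pericyte genes 3 fell (3 adjusted over the list alone; adjusted p = 0.818). Mylk was called lower with 0 of 4 DTG arrays above background, but it read 0.04 with normexp, and its Control mean, -5.67, also lay below that DTG level. Lmod1 read -0.86 (adjusted p = 0.054). Synpo2 fell by 0.81 on a probe with values on 2 Control arrays. A dimmer probe read 0.21, and stood for the gene without Control 3 (0.21) or Control 4 (0.24). Of 21 endothelial genes 1 rose and 3 fell (1 and 2 adjusted over the list alone; adjusted p = 0.818). Tie1 rose by 1.09 and Cldn5 fell by 0.72, while Vwf and Egfl7 fell by 0.45 and 0.29 and were above 0 on the spike-in scale. Of 13 melanocyte genes 3 fell (0 adjusted over the list alone; adjusted p = 0.669). Mlana fell by 1.21, Tyr and Sox10 by 0.29 and 0.47 with values above 0 on the spike-in scale, and Dct read -0.49 (adjusted p = 0.12).

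Among immune cells, 6 of 27 lymphocyte genes fell and 1 rose (the same adjusted over the list alone; adjusted p = 0.429). The T cell receptor complex genes Cd3g, Cd3e and Cd3d fell by 0.81 (SE 0.11), 0.74 (SE 0.13) and 0.72 (SE 0.15), and the cytotoxic granule gene Nkg7 by 0.83 (SE 0.12). Of 25 macrophage and dendritic cell genes 1 rose (0 adjusted over the list alone, camera adjusted p = 0.364), Mrc1 by 0.39, whereas Csf1r read -0.27, Itgax 0.35 and Cd207 -0.30. The other Csf1r probes read 0.33 (SE 0.45) and 0.20 (SE 0.12), and were not called. None of 13 mast cell genes (adjusted p = 0.818), 29 interferon response genes (adjusted p = 0.868) or 9 erythrocyte genes (adjusted p = 0.957) passed, nor did any adjusted over the list alone. The smallest p belonged to Slc18a2 (-0.31) in the mast cell list and to Klf1 (-0.26) in the erythrocyte list. Of the 17 circadian clock genes, a further check on sampling, 1 fell (0 adjusted over the list alone; adjusted p = 0.408). Of 14 housekeeping genes 1 rose (1 adjusted over the list alone, camera adjusted p = 0.952), Tbp by 0.66 with a second probe at 0.81 (SE 0.35) that was not called. B2m, Tfrc and Eef2 read -0.24, -0.29 and -0.19, and the other Tfrc probes read -0.34 and 0.09.

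Epidermal and hair follicle lists also held changes in both directions. Of 15 basal keratinocyte genes 5 fell (5 adjusted over the list alone; adjusted p = 0.818). The hemidesmosome genes Col17a1 and Itgb4 fell by 0.61 (SE 0.11) and 0.81 (SE 0.16). Krt5 fell by 0.59, with 0.12 on its other probe, and Krt15 by 0.38, with 0.12 on the spike-in scale. Of 32 cornified envelope and epidermal differentiation genes 3 rose and 5 fell (the same adjusted over the list alone; adjusted p = 0.904). The transglutaminase gene Tgm5 fell by 1.55 (SE 0.19) and Lce1m by 0.65 (SE 0.14), while the transcription factor genes Grhl3 and Ovol1 rose by 1.16 (SE 0.26) and 0.88 (SE 0.13). Of 22 hair follicle stem cell genes 3 rose and 8 fell (3 and 10 adjusted over the list alone; adjusted p = 0.952). Aldh3a1 fell by 2.26 (SE 0.16) and the transcription factor gene Lhx2 by 0.55 (SE 0.09). Runx1 rose by 0.84, with a second probe at 0.52 (SE 0.18) that was not called, and Plet1 by 0.67. Of 34 hair shaft and inner root sheath genes 5 rose and 5 fell (the same adjusted over the list alone; adjusted p = 0.818). Tchh, the inner root sheath protein trichohyalin, rose by 1.30 (SE 0.17), and Krtap3-2 and Krtap19-5 fell by 1.51 and 0.63. Krtap11-1 rose by 1.21, with -0.06 on its other probe. Of 23 sebaceous gland genes 3 rose and 2 fell (3 and 1 adjusted over the list alone; adjusted p = 0.818). Dhrs9 was 4.01-fold higher, the wax synthase gene Awat2 rose by 1.12 (SE 0.18) and Far2 by 0.31, and Fa2h fell by 0.53. Of 17 dermal papilla genes 1 rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.818). Alpl, an alkaline phosphatase gene, rose by 1.42 and Enpp2 fell by 0.56. The test pointed opposite to the list median relative to all genes for hair shaft, sebaceous gland, interferon response and smooth muscle genes. For Notch, housekeeping and erythrocyte genes the mean lay above the median of all genes, opposite to the list median and the test. The lists' own mean and median, not taken relative to all genes, differed in sign for the sebaceous gland (0.01 and -0.19), dermal papilla (0.01 and -0.10), erythrocyte (0.01 and -0.21) and circadian clock (-0.08 and 0.02) lists.

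Array background, spike-in level and slide row all differed between the groups, and slide row and group cannot be told apart. Without Control 3 the number of genes called lower was 2486 in place of 3778; leaving out any other array moved the counts of called genes by under 1.5 times. Genes that lost their call without at least 1 array included Boc, Cdon, Krt15, Far2, Postn, Fn1, Lum, Fbln1, Tnnt3, Mrc1, Egfl7, Tyr, Mlana, Sox10, Ncmap, Sdhb, Atp5g1, Uqcrc1, Rpl18, Rpl30 and Rpl3.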

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

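The tests with the Xist class, of dim probes, of the scale and of the low Msi1 signal on Control 2 were chosen only after the result was seen. Groups of 4 arrays were checked for the named genes and for 5 array measures. Of 306 groups, 14 (4.58%) held an array standing apart from the other 3, measured as its gap to the nearest of them over the whole range of the group. The cut was a ratio of 0.829, and Msi1 in Control, weighed below, lay just under it at 0.824. Chance gives about 1 in 20. Of the 14, 5 fell on Control 4: Tgfb2 (ratio 0.853, level 0.98 against 1.72 to 1.84), Cd3e (0.870), Hdc (0.895), Ncmap (0.930) and Tfrc (0.875). On the other Control arrays they were Ifit3 (0.898) and Prx (0.873) on Control 2, Bub1b (0.830) on Control 1 and Ier3 (0.831) on Control 3. Among those on the DTG side were Plk2 (0.872) on DTG 1, Bub1 (0.856) on DTG 2, Prx (0.858) on DTG 3 and Aldh3a1 (0.8294) on DTG 4.

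Probes without a gene symbol, which the comparison did not use, also differed between the groups. Of 21963 such probes tested, 6290 (28.6%) were called, 2189 higher and 4101 lower in DTG. In the same fit 29.7% of named probes were called.

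The number of genes called is the first pattern weighed. Of the 35 splits of the 8 arrays into 4 and 4, only the real one, 1 split, called as many genes (5755, against at most 2 in any other split). That share, 0.0286, is the smallest that 35 splits can give, so a chance division is an unlikely source of the count but is not excluded. Every other split mixed Control and DTG arrays, so any difference between the groups, slide row included, would lower its count. For the number of gene lists a chance division remains open, as 15 of the 35 splits called as many lists (9 in the real split, 19 at most in another). The tables argue against unequal numbers of arrays with high Xist as the whole source, because 91.1% of the calls stayed in the same direction with the Xist class as a covariate. A difference of DTG skin from Control skin and a difference in background, hybridisation or slide row between the arrays both remain open and may both contribute. A difference in tissue sampling is open too. The immediate early and heat shock list, written as a check on it, was called higher in DTG by camera at its preset correlation.

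The surplus of genes lower in DTG is the second. Unequal background of dim probes would end it among genes well above background on all 8 arrays, but there 62.4% of calls were still lower, and 58.6% at the lowest with any one array (Control 3) left out. That argues against dim probes as the whole source, and not as a part. Of all called genes, 562 had no DTG array and 13 no Control array well above background. Without the filter on dim probes 54.7% of calls were lower. At an absolute log2 fold change of 1 or more 48.9% were lower. The level the arrays are scaled to remains a candidate explanation: with spike-in spots as the scale 6.86% of calls were lower, and without scaling 41.7%. Whether DTG skin held more or less total RNA per amount of spike-in was not tested. The direction of small changes therefore rests on the scale.

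The third is the Msi1 signal on the Control arrays, where Control 2 read -5.92 and the other 3 between -2.26 and -1.48. Traces of DTG RNA on those 3 arrays could lift other genes that are far higher in DTG. On Control 1 the median of 6 such genes, relative to their DTG mean, lay 0.42 above that of Msi1, on Control 3 0.19 below (-0.19) and on Control 4 0.48 below (-0.48), against an SD of 0.45 between Control arrays, which leaves this open because the 6 genes lie near background in Control. The median of the 6 genes relative to their DTG mean was -6.04 on Control 2, and -5.85, -5.67 and -6.04 on Control 1, 3 and 4. The 3 arrays thus showed no lift over Control 2 beyond that SD, but near background a lift could go unseen. A faulty spot on Control 2 is open too, since the array carries 1 spot of the Msi1 probe. No biological explanation was tested for this pattern.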

How the results depend on the processing

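The settings with Xist, spike-in spots, centring on bright genes and kept outlier spots were chosen only after the result was seen. Over up to 26 settings per gene, 3381 of 3849 values of named genes kept their direction and side of the threshold, 375 were weaker, 50 stronger, 14 moved and 29 reversed; of 924 list values, which include both other list tests, 801 were the same, 27 weaker, 24 stronger, 71 moved and 1 reversed. The cell cycle, p53, wound, immediate early and barrier lipid lists were called under all 26 settings tested by camera at its preset correlation, the inflammatory list under 25, Wnt and ribosomal protein under 23 and oxidative phosphorylation under 17. With an estimated correlation camera called none of these lists, and fry did not call the wound, barrier lipid or inflammatory lists. Among the 26 settings, low Xist alone left 1 DTG array, so a list call there rests on no spread within DTG and adds no support. Signal over background limits dim probes most on the DTG arrays.

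Without scaling 3832 genes were called, 1597 of them lower; the cause was not tested. Without the filter on dim probes 3163 were higher and 3820 lower; the cause was not tested. On the spike-in scale 7110 were higher and 524 lower; that scale shifts every gene up. High Xist alone gave 2637 genes (1201 higher, 1436 lower) and low Xist alone 715 (394 and 321), with fewer arrays. A log2 fold change of 1 or more left 1214 (620 and 594) and an adjusted p under 0.01 left 2528 (1032 and 1496), both stricter by construction. Leaving out each array in turn gave 2486 (without Control 3) to 3385 genes called lower, 4070 to 5172 in all, and 8 to 11 lists. Slide column as a block gave 4345, 4111 of them among the 5755. Averaging its probes took Msi1 to 2.50 (limma adjusted p = 0.060), where DTG 1 had only the probe that did not move. On the probe that moved, the change was 6.99 with the column block and stayed between 5.77 (without Control 2) and 7.75 (high Xist alone) under the other settings. With every probe on its own the same probe was counted, having the smaller p, and the other Msi1 probe read -0.03. With an estimated correlation camera called 0 lists (1 at an unadjusted p under 0.05), against 9 with the preset one (11 unadjusted), and fry called 13.

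Genes called lower that turned positive on the spike-in scale, which shifts every gene up, were Boc (0.15), Krt15 (0.12), Postn (0.11), Fn1 (0.10), Lum (0.18), Fbln1 (0.18), Tnnc1 (0.0010), Eno3 (0.034), Tnni2 (0.088), Tnnt3 (0.14), Vwf (0.037), Egfl7 (0.19), Tyr (0.20), Sox10 (0.018), Sdhb (0.16), Atp5g1 (0.16), Uqcrc1 (0.23), Rps18 (0.065), Rpl18 (0.10), Rpl30 (0.062) and Rpl3 (0.14). The oxidative phosphorylation list turned there in its test, although the median of the 33 members in that test, relative to all genes, was -0.064 there and -0.065 with the scale used. Mylk read 0.040 with normexp; the cause was not tested. Synpo2, whose brighter probe had values on 2 Control arrays, read -0.85 to 0.24 with an array left out. A dimmer probe stood for it in the authors' deposited values (0.24), with low Xist alone (0.81), without Control 3 (0.21) and without Control 4 (0.24). As an average it read 0.97, with the dimmer probe alone on Control 1 and Control 2. With outlier spots kept it read -0.90. Msi2 read 0.27 as an average and 1.09 with every probe on its own, as its probes disagree.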

Other observations

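The symbol-stem groups and the list medians under other splits were tested only after the result was seen, and the genes in them were chosen after their values were seen. Grouping named genes by the letters that start their symbols gave 286 groups of at least 8 genes, of which 7 were called by camera, 4 higher and 3 lower, and 0 with an estimated correlation (adjusted p = 0.992 for each of the groups given here). Own medians of the groups that rose lay above 0 under each scaling. Their medians relative to all genes lay above 0 with quantile scaling too, the only other scaling that can move them. Of 14 proteasome-related genes whose symbols start with Psmd, 9 rose and 0 fell, led by Psmd14 at 1.89 (SE 0.33) and Psmd6 at 0.78 (SE 0.10). Of 12 small proline-rich genes of the cornified envelope (Sprr), 9 rose and 1 fell, with Sprr2k at 2.06 (SE 0.56) and Sprr2b at -1.14 (SE 0.29). Of 8 small nucleolar RNA host genes (Snhg), 5 rose and 0 fell, led by Snhg16 at 1.81 (SE 0.13) and Snhg7 at 1.37 (SE 0.13).

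Of 10 secretoglobin genes, 7 rose and 2 fell: Scgb1b24 read 3.37 (SE 0.41; 2 of 4 Control arrays above background) and Scgb1c1 2.83 (SE 0.19), while Scgb1b27 and Scgb1b30 read -3.04 and -2.54. Of 18 Wnt ligand genes 13 fell and 1, Wnt2b, rose by 0.60. The group's own median, -0.47, was 0.01 on the spike-in scale. Relative to all genes the Wnt ligand median was -0.33 with the scale used and -0.37 with quantile scaling. Of 10 Skint genes, which are expressed in epidermis and thymus, 5 fell and 0 rose, but the group was not called (adjusted p = 0.108). Skint1 read -0.96 (SE 0.17). Of 433 olfactory receptor genes 133 fell and 6 rose, and 290 of the 433 were not above background on all 8 arrays. The group's own median was -0.42, and 0.06 on the spike-in scale. Relative to all genes the median was -0.27 with the scale used and -0.21 with quantile scaling. Of 43 Rpl genes 18 fell and 1 rose, with an own median of -0.32 that was 0.17 on the spike-in scale. Relative to all genes the Rpl median was -0.17 with the scale used but -0.0003 with quantile scaling, where the fall vanished.

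Across the 35 splits of the arrays, the real one gave the farthest list median, relative to all genes, for the cell cycle, inflammatory, p53, wound, immediate early, barrier lipid and Wnt lists (exact share 0.0286 each, adjusted over the lists 0.0943). The same held for the adipocyte, Schwann cell and nerve, and dermal extracellular matrix lists, which camera did not call. It ranked 4 for ribosomal protein and 7 for oxidative phosphorylation genes. Every other split mixed Control and DTG arrays, so any difference between the groups, slide row included, would tend to shrink its medians. The genes were also filtered with the real groups. This ranking therefore cannot tell a change of a list in DTG skin from a technical difference between the groups.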
